A study of Mus musculus with 2 samples.

How the data were processed

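The samples were 2 droplet libraries of dissociated mouse aorta (ascending aorta, arch and descending thoracic aorta), 1 for the Ctrl and 1 for the M-LipaKI group, each pooled from 3 male mice and sorted as viable nucleated singlets by DRAQ5 and DAPI staining. Groups were taken from the sample titles and genotypes. Per the labels, the libraries were made with a 10x Genomics 3′ kit. The deposited files hold whole UMI counts per gene and barcode that the authors had not normalised. The matrix headers name Cell Ranger 6.1.2, while the submitters' processing notes name Cell Ranger 3.0.1, Seurat 4.3.0.1 and the mm10 build. How the authors chose the deposited barcodes is not given in the sources used here, and the lowest barcodes held 501 and 500 UMIs. No deposited annotation of cells was used, so all cell names are rebuilt and can differ from those of the study.

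Of 32285 genes, 32158 were matched by identifier to GENCODE M21 annotation of the same build, from which coordinates were taken. Barcodes with under 200 genes (284 in Ctrl, 171 in M-LipaKI) or with over 10% of UMIs from mitochondrial genes (486 and 560) were removed. Doublets were scored per library with Scrublet as run by scanpy 1.11.5 at an expected rate of 0.008 per 1000 barcodes. Its automatic threshold marked 0.209% of Ctrl barcodes, which was taken as a failure, so there the highest scores up to the expected 4.72% were removed. In M-LipaKI the automatic threshold marked 3.02%. In all 247 and 176 further barcodes were removed, leaving 4887 and 5547 cells with 73636994 and 85637775 UMIs. The kept cells had a median of 4.76% and 3.80% mitochondrial UMIs. The libraries shared 21 barcodes.

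Kept cells of both libraries were clustered together without batch correction: counts per 10000 were log-transformed, 2000 variable genes (without Lipa, Lyz2, Xist, mitochondrial and antigen receptor genes) gave 30 principal components and a graph of 15 neighbours, and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) was run at resolution 1.0. Clusters were named from fixed marker lists, needing at least 3 detected markers and leading genes that go with the name. Macrophages were clustered again at resolution 0.6 into 6 states. Monocytes, neutrophils, dendritic cells, T cells and B cells formed no cluster of their own, and the mixed immune cluster 14 stayed unnamed. The 4 classes with at least 100 cells in each library, namely macrophages, smooth muscle cells, modulated smooth muscle cells and fibroblasts, were compared.

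UMIs were summed per class and library and given as CPM, UMIs of a gene over all UMIs of its class on the usual CPM scale. Levels carry exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact conditional binomial intervals, all at 95%. Because each group has 1 library, no test was made and no p-value is given. Gene lists fixed beforehand were summarised, where 5 or more members had at least 20 UMIs over both libraries, as the median log2 ratio of members minus that of all measured genes. Each was set beside 10000 random lists of the same size drawn from 20 expression bins, which describes these libraries only. The modulated smooth muscle class was read with the smooth muscle lists. Of the listed genes, 1 (Mx1) was missing from the files. Lists written for classes that were not compared (endothelial and T cell lists) gave no value.

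Genes were named by rule: in macrophages the 12 highest and 12 lowest log2 ratios, and in each other class the 3 highest and 3 lowest. They needed at least 100 UMIs over both libraries, a counting interval that excludes a ratio of 1, and a CPM in the class of at least 0.5 of that in all other kept cells. Mitochondrial, ribosomal protein, haemoglobin, antigen receptor and clone-named genes were left out. Lipa, Lyz2 and Ldlr were always reported, and from each list members with the most UMIs or the largest ratio were given. Members outside this rule that are mentioned, such as Abca1, Il1b and Cxcl9, were chosen after their values were seen. Grouping, filters, marker and gene lists, the naming rule and the alternatives were set before the data were examined, except for the alternatives named as later additions in the closing section.

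The steps were tested on simulated data drawn from the real class totals. For the comparison of macrophages, with 8207 genes in the step, 50 genes each at simulated log2 ratios of 1, -1, 2 and -2 were found at medians of 0.95, -0.98, 2.00 and -1.99. Intervals held the true value in 92% to 100% of changed genes and 95.6% of unchanged genes. A list simulated with a shift of 0.5 was found at 0.49, and one without at -0.02. Such simulations hold counting error only.

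Alternatives were mitochondrial limits of 5% and 20%, a minimum of 500 genes, doublets kept, Leiden resolutions of 0.5 and 2.0, standardising genes within each library, TMM factors (edgeR 4.0.16 in R 4.3.3), median-of-ratios factors, totals without genes over 1% of UMIs, means of per-cell CPM, thinning cells to 5000 UMIs, other UMI minimums, means of per-state log2 ratios, other sub-clustering resolutions and shares among immune cells. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.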

Results

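Aortic cells of Ldlr-deficient mice, which develop atherosclerosis on a fat-rich diet, were profiled by droplet-based single-cell RNA sequencing with 1 library per group. The M-LipaKI library came from mice carrying a Cre-dependent Lipa transgene and LysM-Cre, a Cre gene placed in the Lyz2 locus that is active in myeloid cells. The Ctrl library came from littermates with the transgene and no Cre. Effects of Lipa overexpression therefore cannot be told apart from those of Cre or of its insertion in Lyz2. Lipa encodes lysosomal acid lipase, the enzyme that hydrolyses cholesteryl esters and triglycerides in lysosomes, and the comparison asks how its overexpression in myeloid cells changes the cells of the diseased aorta. Each library pooled 3 male mice after 16 weeks of Western diet. The Ctrl library held 5904 barcodes with 80807686 UMIs and the M-LipaKI library 6454 barcodes with 92034045 UMIs. After filtering, 4887 and 5547 cells remained, with medians of 14754 and 14857 UMIs per cell. With 1 library per group, no difference given here has a replicate check and none was tested. All intervals are 95% intervals that cover counting error only, so differences between mice, digestions and sorts lie outside them.

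The first comparison was of the cell classes in each aortic digest. Smooth muscle cells made up 58.3% of kept Ctrl cells (2848 of 4887; 56.9 to 59.7) and 44.8% of M-LipaKI cells (2486 of 5547; 43.5 to 46.1), a ratio of 0.769 (0.728 to 0.812). Fibroblasts made up 21.9% of Ctrl and 29.5% of M-LipaKI cells, a ratio of 1.35 (1.24 to 1.45). Macrophages made up 8.86% (433 cells) and 11% (611 cells), a ratio of 1.24 (1.10 to 1.41). Modulated smooth muscle cells, which express matrix and cartilage genes in place of part of the contractile programme, made up 5.07% and 7.05%, a ratio of 1.39 (1.18 to 1.64). Within this class, cluster 12, led by Thbs1, Igfbp2 and Col8a1, held 1.13% of Ctrl and 3.35% of M-LipaKI cells. Cluster 19, led by the cartilage and bone genes Ibsp, Col2a1 and Chad, held 0.921% and 0.325%. Endothelial cells were 0.552% (27 cells) and 0.937% (52 cells), and mesothelial cells numbered 6 and 9. Shares of a library add up to a whole, so the lower smooth muscle share by itself raises the other shares. The ratios of the classes are therefore not independent of each other.

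Clusters without a class name held small shares. Cluster 13, led by Sfrp2 and Rgs5, held 2.64% of Ctrl and 1.95% of M-LipaKI cells, and cluster 16, led by the fibroblast genes Pi16 and Serpinf1, held 0.778% and 0.955%. Cluster 16 also had the smooth muscle gene Acta2 at 16968.5 CPM beside the fibroblast gene Dcn at 6255 CPM. Its median doublet score (0.086) was the highest of all clusters, and whether it holds doublets was not tested. The cycling cluster 20 held 0.368% and 0.775%. The mixed immune cluster 14, led by Cd74 and the MHC class II genes H2-Eb1 and H2-Aa, held 0.880% and 1.57%, and cluster 18, a shallow cluster led by the stress genes Hmox1, Hspa5 and Ddit3, held 0.307% and 1.10%. A further 10 Ctrl and 9 M-LipaKI cells that grouped with macrophages were led by Tagln and Acta2 and were left out. Among macrophages and cluster 14 together, macrophages were 91.0% of Ctrl and 87.5% of M-LipaKI cells, a ratio of 0.962 (0.849 to 1.09). This denominator is mostly macrophages, so the ratio compares them with cluster 14 and does not measure their share of aortic cells. The higher macrophage share ended with a mitochondrial limit of 5%, where its log2 ratio was -0.01. That limit kept 6240 cells and removed most smooth muscle cells, so the denominator changed. Median mitochondrial shares were 5.90% and 5.68% in Ctrl and M-LipaKI smooth muscle cells, against 2.76% and 2.92% in macrophages. With that limit the fibroblast share stayed higher in the M-LipaKI library, but its ratio fell below its counting interval. The log2 ratio of the modulated smooth muscle share went from 0.47 to 0.05 when genes were standardised within each library before clustering.

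**Figure D1:**
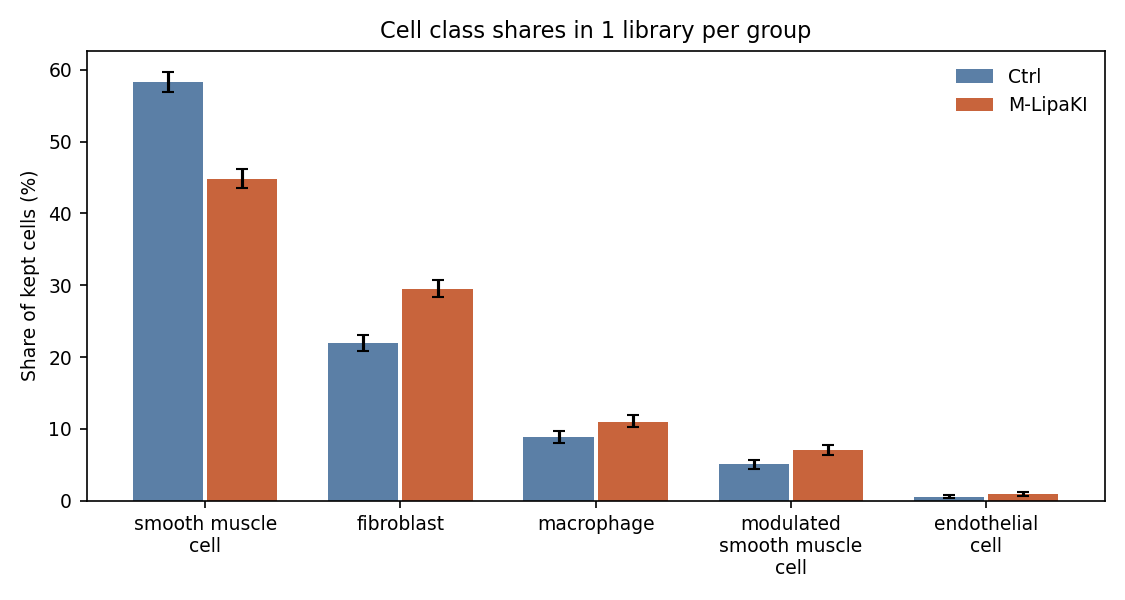
Share of kept cells (%, vertical axis) in each named class for the Ctrl and M-LipaKI libraries; bars are the shares and error bars exact binomial 95% intervals, which cover counting error only. Smooth muscle cells were 58.3% of Ctrl and 44.8% of M-LipaKI cells, and the fibroblast, macrophage and modulated smooth muscle shares were higher in the M-LipaKI library. Shares add up to a whole, so the lower smooth muscle share by itself raises the others.

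The genes altered by the genotype were read next. Lipa (ENSMUSG00000024781, chromosome 19, 34492318 to 34527474, minus strand) was at 248 CPM (235 to 261) in Ctrl macrophages and 281 CPM (270 to 293) in M-LipaKI macrophages, a ratio of 1.14 (1.06 to 1.21). By state, Lipa was at 410 and 560 CPM in Gpnmb-led lipid-associated-like macrophages (ratio 1.37, 1.20 to 1.56) and at 203 and 265 CPM in Vsig4-led resident-like macrophages (1.30, 1.11 to 1.54). In Retnla-led resident-like macrophages it was at 275 and 239 CPM (0.870, 0.743 to 1.02). After every cell was thinned to 5000 UMIs, which left out 21 shallower macrophages of each library, the log2 ratio of Lipa in macrophages went from 0.18 to 0.03, and 61.2% of Ctrl and 62.7% of M-LipaKI macrophages had a Lipa UMI (82.9% and 89.7% without thinning). Smooth muscle cells, where Lipa is low, had a Lipa UMI in 340 of 2826 and 318 of 2462 thinned cells, from unthinned medians of 16363 and 17385 UMIs against 11193 and 11384 in macrophages. In smooth muscle cells (26.3 and 27.7 CPM), fibroblasts (93.1 and 95.3 CPM) and modulated smooth muscle cells (35.5 and 36.6 CPM) the intervals of the Lipa ratio included 1. The transgene is a cassette in the Rosa26 locus and a tag at the transcript's 3′ end can miss it, so these Lipa levels do not check the labels. Ldlr, disrupted in both groups, had 16 UMIs in the macrophages of each library and was at 1.93 and 2.77 CPM in fibroblasts, 4.62 and 3.80 CPM in smooth muscle cells and 3.08 and 2.21 CPM in modulated smooth muscle cells.

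Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321, minus strand), which encodes macrophage lysozyme and carries the Cre insertion, was at 10732 CPM in Ctrl and 6312 CPM in M-LipaKI macrophages. The ratio was 0.588 (0.581 to 0.595), and Lyz2 was lower in each of the 6 macrophage states, from a ratio of 0.517 in Gpnmb-led to 0.777 in proliferating cells. Lyz2 was at 26.0 and 15.6 CPM in fibroblasts, 11.3 and 8.42 CPM in smooth muscle cells and 10.4 and 17.9 CPM in modulated smooth muscle cells. Its neighbour Lyz1 (ENSMUSG00000069515, chromosome 10, 117287797 to 117292868, minus strand), the other mouse lysozyme gene, was at 42.7 CPM (37.4 to 48.6) in Ctrl and 753 CPM (734 to 772) in M-LipaKI macrophages. This was a 17.6-fold difference (15.5 to 20.2), and Lyz1 was higher in each of the 6 states. Lyz1 UMIs came from 24 of 433 Ctrl and 205 of 611 M-LipaKI macrophages. The 5 highest cells held 88.1% of them in the Ctrl library and 43.6% in the M-LipaKI library. In thinned cells 4.13% of Ctrl and 26.3% of M-LipaKI macrophages had a Lyz1 UMI, against 0.406% of M-LipaKI smooth muscle cells. Lyz1 and Lyz2 are close paralogs, and reads that fit both may have been counted to either. In Ctrl macrophages 59016 Lyz2 UMIs stood beside 235 Lyz1 UMIs, so few Lyz2 reads of that library can have been counted as Lyz1.

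**Figure D2:**
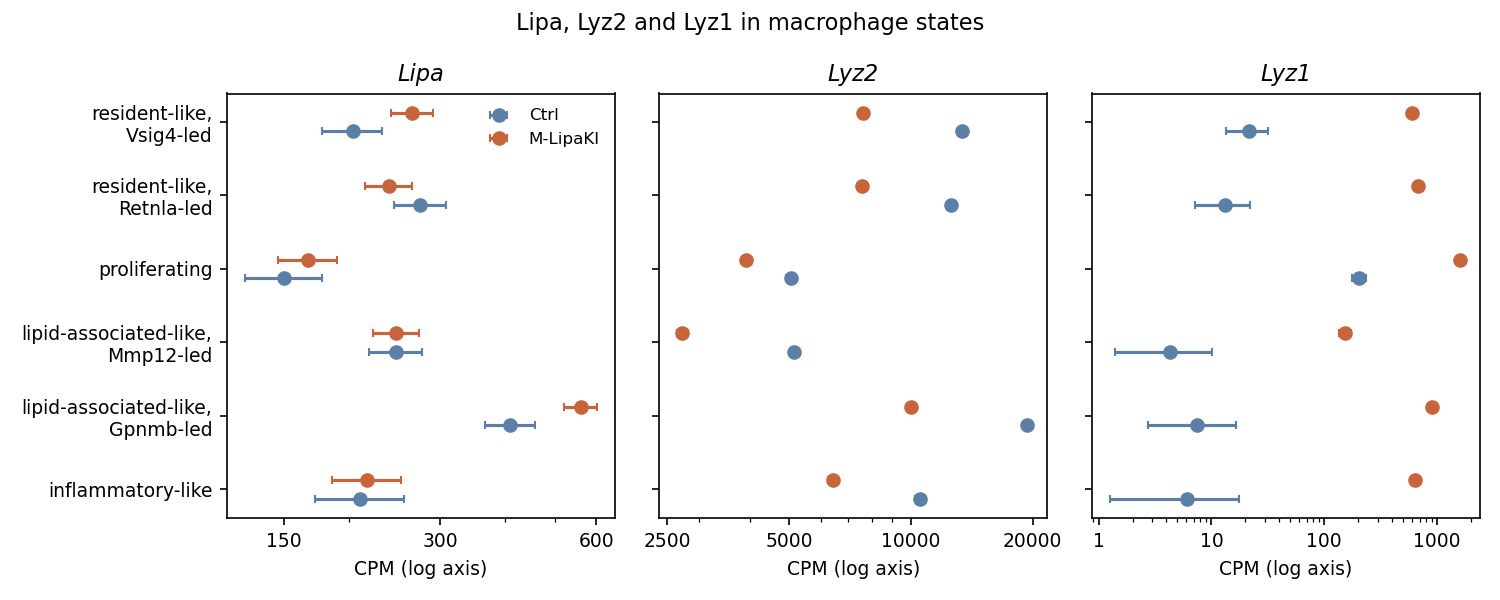
CPM (log axes) of Lipa, Lyz2 and Lyz1 in the 6 macrophage states of the Ctrl and M-LipaKI libraries; points are CPM from summed UMIs and error bars exact Poisson 95% intervals. Lyz2 was lower and Lyz1 higher in the M-LipaKI library in each state, while Lipa in Gpnmb-led macrophages was at 410 and 560 CPM.

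Macrophages were divided into 6 states, and their shares did not differ detectably at this depth. Resident-like macrophages led by Vsig4 or Retnla together made up 49.2% of Ctrl and 49.3% of M-LipaKI macrophages, a ratio of 1.00 (0.837 to 1.20). Lipid-associated-like macrophages led by Mmp12 or Gpnmb made up 28.4% and 28.2%, a ratio of 0.991 (0.782 to 1.26). Proliferating macrophages were 11.3% and 11.5%, and inflammatory-like macrophages, with the interferon-induced Ifit2 and Ifit3 among their leading genes, were 11.1% and 11.1%. The shares of the 6 states lay closer together than counting error alone usually gives (chi-square 0.065 on 5 degrees of freedom). With 10 neighbours in the graph, which gave 10 sub-clusters, the value was 6.96 on 9. No barcode's counts were identical to another's among 12358.

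Genes named by rule in macrophages were led by lysozyme, lipid-associated, interferon and heat shock genes. After Lyz1, the highest log2 ratios of M-LipaKI over Ctrl were 1.84 (1.66 to 2.03) for Gpnmb, a glycoprotein of lipid-laden macrophages, and 1.82 (1.52 to 2.13) for Cxcl10, an interferon-induced chemokine. Ctsk, a lysosomal cysteine protease, stood at 1.65 (1.45 to 1.84). Among interferon-induced genes Rsad2 was at 1.43 (1.05 to 1.83), the transcription factor Irf7 at 1.23 (0.96 to 1.51) and Isg15 at 1.13 (0.90 to 1.37). The inducible Hsp70 genes Hspa1b and Hspa1a, near-identical copies of each other, were at 1.35 and 1.27. Csprs (1.16), Ppat, the first enzyme of purine synthesis (1.15), and Tmem178 (1.11) completed the higher genes. Irf7 UMIs came from 81 Ctrl and 181 M-LipaKI cells, with at most 20 in 1 cell.

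Several of these levels rested on few cells, for which counting intervals are too narrow because UMIs of 1 cell are not independent. The Gpnmb ratio used 287 and 1534 UMIs, and the 5 highest M-LipaKI cells held 71.6% of the latter. Without the 5 highest cells of each library its log2 ratio was 0.99 (0.72 to 1.27). Without such cells the log2 ratio was 2.38 for Ctsk, 0.96 for Cxcl10 and 6.38 for Lyz1. For Ctsk and Lyz1 the 5 highest cells held 74.3% and 88.1% of Ctrl UMIs but 57.1% and 43.6% of M-LipaKI UMIs. Leaving them out thus lowered the Ctrl level more, and both ratios rose.

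Named genes lower in M-LipaKI macrophages had few UMIs, as did Csprs, Ppat and Tmem178 among the higher genes. The mast cell proteases Mcpt4 (log2 ratio -7.26) and Cma1 (-6.21) came from 1 Ctrl cell in 101 of 103 and 149 of 149 Ctrl UMIs, and Cma1 turned to 1.42 with doublets kept. The others were Ppp1r1a (-1.11, -1.55 to -0.68), the interleukin receptor subunit Il2ra (12.2 and 6.09 CPM), the secreted phospholipase Pla2g2d (-0.97, -1.29 to -0.66), Depdc7 (-0.95) and the DNA repair gene Rad51b (-0.88). Fcrl1 (-0.85), the peptide transporter Slc15a2 (-0.83), the arginine synthesis enzyme Ass1 (-0.82), Cd5 (-0.81) and the inflammasome sensor Nlrp1b (-0.81) followed. Pla2g2d UMIs came from 82 Ctrl and 67 M-LipaKI cells. The middle 95% of the 8207 genes with at least 100 UMIs in macrophages lay between -0.40 and 0.51.

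Interferon-stimulated genes were higher together in M-LipaKI macrophages. Of 25 measured members 24 lay above the median of all genes, and the list's median lay 0.56 above it (0.40 to 0.70), at the 100th percentile of 10000 random lists matched on expression. Without the 10% of cells with the highest list share it was 0.29 (0.22 to 0.41). Cxcl10 was at 19.3 and 68.0 CPM in the Ctrl and M-LipaKI macrophages, Rsad2 at 12.7 and 34.3 CPM, and the more abundant Bst2, an antiviral membrane protein, at 368 and 467 CPM. The 1 member below, the chemokine Cxcl9 (log2 ratio -5.45), was chosen for mention after its values were seen and had 87 of its 88 Ctrl UMIs in 1 cell. The shift was 1.17 (0.89 to 1.47) in proliferating macrophages, 0.98 in Gpnmb-led, 0.78 in inflammatory-like, 0.43 in Retnla-led and 0.28 in Vsig4-led macrophages. In Mmp12-led macrophages it was -0.08 (-0.43 to 0.14). The dissociation stress list moved in the same direction in the class, with a shift of 0.10 (0.04 to 0.15), led by Hspa1b and Hspa1a.

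Lists for lipid handling and energy use shifted less. Lipid uptake, storage and hydrolysis genes had a median shift of 0.11 (0.04 to 0.17), with 14 of 18 members above and a percentile of 99.1. The fatty acid carriers Fabp4 and Fabp5 were at 6.55 and 16.0 CPM and at 368 and 417 CPM, and the lipid droplet protein Plin2 at 372 and 397 CPM. This shift was 0.39 (0.15 to 0.67) in Gpnmb-led macrophages, with intervals that included 0 in the others: 0.13 in Vsig4-led, 0.06 in proliferating, 0.04 in Mmp12-led, -0.05 in Retnla-led and -0.23 (-0.54 to 0.01) in inflammatory-like macrophages. Glycolysis genes had a shift of 0.10 (0.03 to 0.17), with 14 of 17 above, among them the glucose transporter Slc2a1 (log2 ratio 0.72), and fatty acid oxidation genes one of 0.09 (-0.00 to 0.16) at percentile 98.2. Matrix remodelling genes stood at 0.07 (0.00 to 0.12), inside the middle 95% of random lists (percentile 96.6), with 15 of 23 above, although Spp1, the member with the most UMIs, was at 5530 and 4973 CPM.

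Lysosomal genes differed in direction between macrophage states. Their median shift was 0.00 (-0.03 to 0.03) for the class, with 24 of 46 above, but -0.15 (-0.21 to -0.08) in proliferating, -0.15 (-0.18 to -0.08) in Mmp12-led and 0.11 (0.03 to 0.18) in inflammatory-like macrophages, each outside the middle 95% of random lists. In the class Ctsk, Acp5 (28.6 and 40.8 CPM) and Ctsd (log2 ratio 0.24) were higher. LXR targets and cholesterol efflux genes had a shift of -0.00 (-0.09 to 0.07) for the class and -0.25 (-0.44 to -0.06) in proliferating macrophages, with 3 of 15 above, and in the class Abca1 was at 406 and 357 CPM and Pltp at 812 and 942 CPM. Sterol synthesis genes were at -0.08 (-0.24 to 0.05), percentile 13.3, with 12 of 22 members below, and at -0.44 (-0.75 to -0.09), percentile 0.535, in Gpnmb-led macrophages, where 10 members were measured. Inflammatory cytokine and NF-kB genes were at -0.01 (-0.09 to 0.08), with 14 of 28 above. In this last list Tnf was at 32.4 and 48.3 CPM, while the monocyte chemokine Ccl2 was at 712 and 611 CPM and Il1b at 85.3 and 76.6 CPM. The autophagy list was at 0.01, efferocytosis at -0.03, integrins at 0.03, cell cycle at -0.00, antioxidant and iron genes at -0.02, complement at -0.04, oxidative phosphorylation at -0.04, ERK targets at -0.03 and recruitment receptors at -0.06.

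Antigen presentation genes were lower in M-LipaKI macrophages as a class. MHC class II genes had a shift of -0.16 (-0.21 to -0.03), percentile 0.255, with 8 of 11 below. The invariant chain gene Cd74 was at 4475 and 3857 CPM and H2-Eb1 at 1641 and 1406 CPM. The direction differed by state: the MHC class II shift was -0.55 in inflammatory-like, -0.41 in Vsig4-led and -0.29 in Mmp12-led macrophages, and 0.61 in Gpnmb-led and 0.64 in proliferating macrophages. Unfolded protein response genes had a shift of -0.09 (-0.11 to 0.01), percentile 2.57, with 10 of 15 below, although the stress-induced Ddit3 was at 35.5 and 45.9 CPM.

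**Figure D3:**
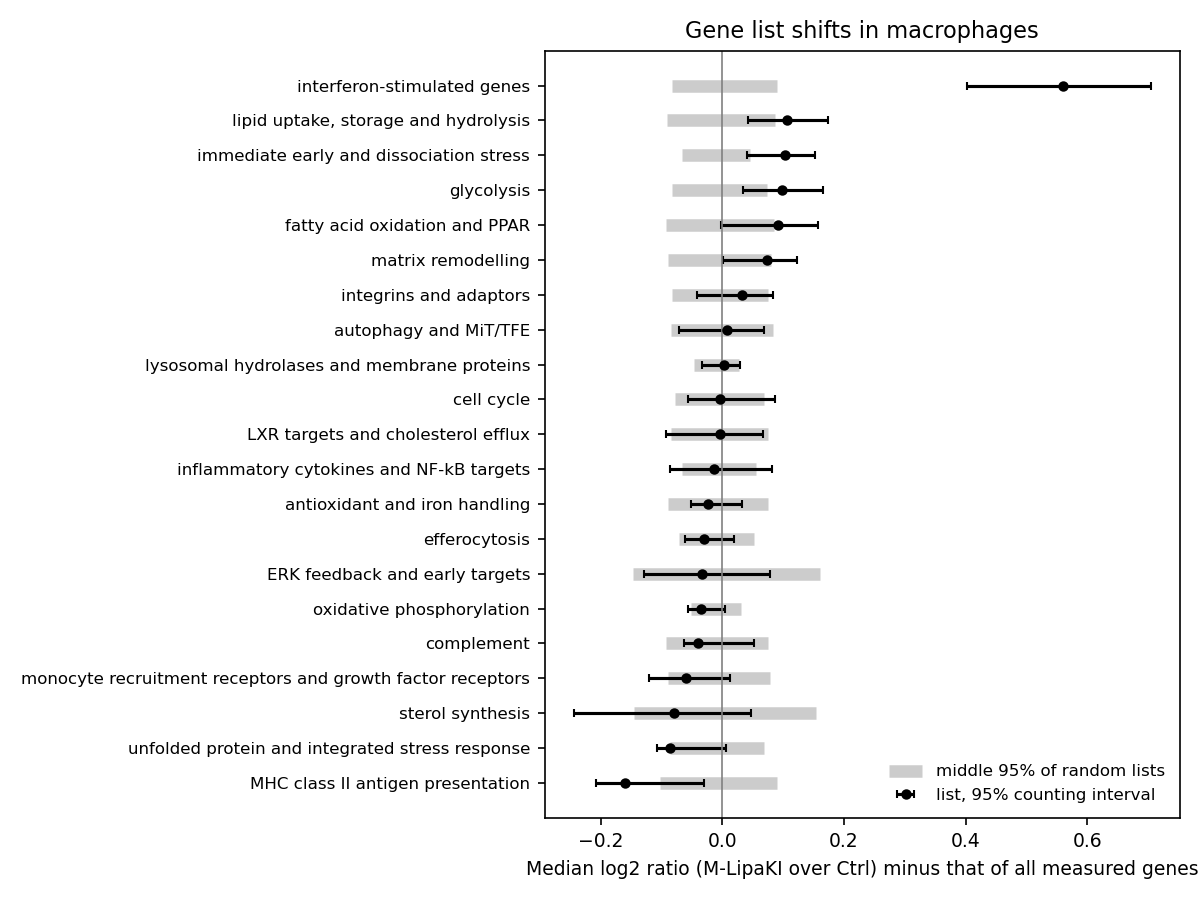
Median log2 ratio of each gene list in macrophages minus that of all measured genes (horizontal axis); points are lists with 95% counting intervals and grey bars the middle 95% of 10000 random lists matched on expression. The interferon list stood at 0.56, and the MHC class II list, at -0.16, lay lowest.

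Smooth muscle cells, which lie outside the myeloid lineage, were read with the same lists. Interferon-stimulated genes had a shift of 0.27 (0.12 to 0.35), with 18 of 22 above, and Ifi27l2a was at 37.1 and 57.8 CPM. Smooth muscle modulation genes had a shift of 0.13 (0.11 to 0.16), with 18 of 24 above, among them the protease inhibitor Timp1 at 114 and 232 CPM and the stem cell antigen Ly6a at 9.66 and 26.8 CPM. The contractile list had a shift of -0.01 (-0.02 to 0.00), with Acta2 at 21759 and 21844 CPM. Structural matrix genes were at 0.09, matrix remodelling at 0.13, complement at 0.20, inflammatory cytokines at 0.16 and lysosomal genes at 0.07, each with a counting interval above 0, and so were the unfolded protein response (0.11), LXR (0.08) and oxidative phosphorylation (0.05) lists. The stress list was lower, at -0.06 (-0.10 to -0.05). Sterol synthesis (-0.04), lipid uptake (0.04), ERK targets (0.05) and cell cycle genes (0.01) had intervals that included 0.

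These class values moved with the mix of smooth muscle clusters. Cluster 0 was the most numerous in the Ctrl library (833 cells) and cluster 2, with Spp1, Vcam1 and Hbb-bs among its leading genes, in the M-LipaKI library (656 cells). With cluster levels weighted to common cluster shares the interferon shift was 0.013, the modulation shift -0.053, the complement shift -0.031 and the inflammatory cytokine shift -0.0090. With a mitochondrial limit of 5%, which removed most cells of this class, the interferon shift was -0.03 and the complement shift -0.07. When genes were standardised within each library before clustering the interferon shift was 0.40 and the modulation shift 0.39. MHC class II genes had a shift of 0.58 (0.36 to 0.91) from low levels, with Cd74 at 13.2 and 26.7 CPM against 4475 and 3857 CPM in macrophages, and smooth muscle cluster 4 held 47 Ctrl and 496 M-LipaKI UMIs of Cd74, with C1qa at 7.22 and 7.34 CPM. Named genes were Corin, a membrane protease (log2 ratio 1.73), the TNF receptor family gene Tnfrsf9 (1.19) and the glycogen-targeting phosphatase subunit Ppp1r3a (1.14) on the higher side, and Olfr889 (-1.98), Fam184b (-1.24) and Zfp108 (-0.92) on the lower, all below 5 CPM in both libraries.

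Modulated smooth muscle cells differed most in their make-up. The lower named genes Ucma (log2 ratio -3.80), Ibsp (-2.84) and Cnmd (-2.73) are cartilage and bone genes, and Ibsp leads cluster 19, which held 45 Ctrl and 18 M-LipaKI cells. At common cluster shares the log2 ratio of Ibsp was -1.03. The higher named genes were the protease inhibitor Slpi (3.91) and the chemokines Cxcl5 (3.87) and Ccl5 (3.36), and for each of them 1 M-LipaKI cell held a large part of the UMIs (167 of 255, 131 of 292 and 324 of 442). Most cells were in cluster 11 in the Ctrl library, and in clusters 11 and 12 in the M-LipaKI library. The smooth muscle modulation list had a shift of -0.39 (-0.40 to -0.36), with 19 of 24 below, Spp1 at 18887 and 12580 CPM and the cartilage gene Chad at 488 and 103 CPM. At common cluster shares it was -0.042, with shifts of -0.18 in cluster 11 and 0.40 in cluster 12.

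Other lists in modulated smooth muscle cells were read for the class and within clusters. The interferon list had a shift of 0.46 (0.21 to 0.56) for the class, but -0.39 (-0.64 to -0.04) in cluster 11, -0.31 (-0.50 to -0.09) in cluster 12 and -0.21 at common cluster shares. The contractile list had a shift of 0.11 for the class and -0.25 at common cluster shares, and the matrix remodelling list -0.10 and 0.045. MHC class II genes stood at 0.34, again from low levels (Cd74 at 36.1 and 55.1 CPM), and turned to -0.046 at common cluster shares. Macrophage genes were also higher in the class, with C1qa at 6.48 and 20.4 CPM, C1qb at 6.80 and 23.2 CPM and Lyz2 at 10.4 and 17.9 CPM. Whether the same cells held these and the MHC class II genes was not tested. The stress list stood at 0.13, and at -0.030 when genes were standardised within each library before clustering. Inflammatory cytokines (-0.10), complement (-0.14), LXR targets (-0.06), sterol synthesis (-0.04), lipid uptake (0.00), lysosomal (0.01), unfolded protein (0.03), ERK (0.11) and cell cycle genes (0.16) had intervals that included 0. Of these, inflammatory cytokines (percentile 1.58) and complement (percentile 1.075) lay below the middle 95% of random lists. Structural matrix genes (0.06, percentile 81.5, and -0.029 at common cluster shares) and oxidative phosphorylation genes (0.03, percentile 61.8, and -0.015 in thinned cells) had counting intervals above 0 but lay inside the middle 95% of random lists.

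Fibroblasts, the matrix-producing cells of the outer vessel wall, were read with the same lists. The interferon list had a shift of 0.16 (0.08 to 0.30), with 16 of 25 above, Ifi27l2a at 700 and 1049 CPM and Igtp at 9.87 and 16.5 CPM. It was 0.30 with means of per-cell CPM, 0.34 in thinned cells and 0.13 at common cluster shares. Thinning left out 462 of 1072 Ctrl and 509 of 1637 M-LipaKI fibroblasts, so it changed the set of cells as well as the depth. Median depth was 6374.5 UMIs in Ctrl and 9044 in M-LipaKI fibroblasts, and the shallow cluster 6 held 381 of 1072 and 392 of 1637. The interferon shift was 0.50 (0.24 to 0.70) in cluster 10, where the stress list was at 0.35. For the class the stress list was at 0.09 (0.06 to 0.16), with Hspa1a at 52.4 and 144 CPM. Lysosomal genes stood at -0.07 (-0.09 to -0.04) and oxidative phosphorylation genes at -0.06. Complement genes stood at -0.10, inside the middle 95% of random lists (percentile 5.16), with C1qb and C1qc higher. Sterol synthesis genes stood at 0.13 (0.01 to 0.27), also inside that range (percentile 96.7), and at -0.015 with means of per-cluster log2 ratios. Inflammatory cytokines (0.14, percentile 99.96) and the unfolded protein response (0.09, percentile 99.55) lay above the middle 95% of random lists, with counting intervals that included 0. Matrix remodelling (-0.03), structural matrix (0.01) and cell cycle genes (-0.06) lay inside it, with intervals that also included 0.

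Of the named fibroblast genes, Ptn, Thbs4 and Pnoc rested on small groups of cells. Ptn, a heparin-binding growth factor, was at 0.361 and 9.89 CPM (log2 ratio 4.78) and the matricellular gene Thbs4 at 0.843 and 20.8 CPM (4.62), with 135 of 330 M-LipaKI UMIs of Thbs4 in 1 cell. The collagen gene Col8a1 was at 23.8 and 71.7 CPM (1.59, 1.37 to 1.81), in 91 Ctrl and 281 M-LipaKI cells. Pnoc (-1.64), Lrmda (-1.37) and the hedgehog inhibitor Hhip (-1.33) were lower, and 67 of 98 Ctrl UMIs of Pnoc were in 1 cell. Lrmda UMIs came from 67 Ctrl and 50 M-LipaKI cells, and Hhip UMIs from 71 and 68. MHC class II genes had a shift of 0.54 (0.34 to 0.85), with Cd74 at 16.1 and 27.8 CPM, and the shift turned to -0.47 with doublets kept. Macrophage genes went both ways in the class, with C1qa at 13.4 and 18.8 CPM and Lyz2 at 26.0 and 15.6 CPM. Cluster 6 alone held 250 of the 441 M-LipaKI Cd74 UMIs and 5 of the 134 in Ctrl, with C1qa at 16.5 and 13.3 CPM, while in cluster 8 Cd74 was lower (45.2 and 20.4 CPM). Cluster 6 had a median of 1443 UMIs per cell.

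**Figure D4:**
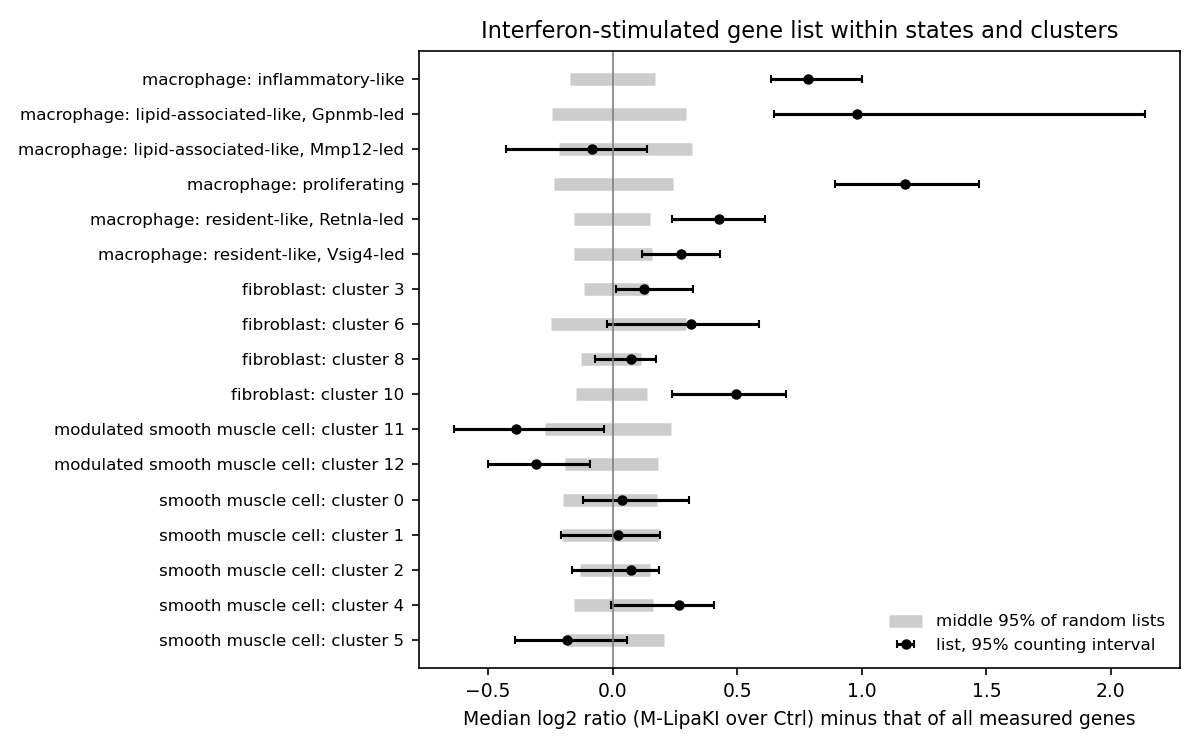
Median log2 ratio of the interferon-stimulated gene list minus that of all measured genes (horizontal axis) within each macrophage state and each cluster of the other classes; points carry 95% counting intervals and grey bars are the middle 95% of random lists. The shift was 1.17 in proliferating macrophages and -0.39 in cluster 11 of the modulated smooth muscle cells.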

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

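The results in this part were picked by 1 of 2 rules, a list shift whose counting interval lies above 0 in one class and below 0 in another, or cells outside the compared classes. The difference was not tested in any of them, since each group has 1 library. MHC class II genes were higher in M-LipaKI fibroblasts (0.54), modulated smooth muscle cells (0.34) and smooth muscle cells (0.58), from low levels, and lower in macrophages (-0.16). The fibroblast value turned to -0.47 with doublets kept and -0.23 with doublets by score rank, and the modulated smooth muscle value to -0.046 at common cluster shares. Smooth muscle cluster 4 held 47 Ctrl and 496 M-LipaKI UMIs of Cd74, with the macrophage gene C1qa at 7.22 and 7.34 CPM, and fibroblast cluster 6 held 5 and 250, with C1qa at 16.5 and 13.3 CPM. C1qa was at 13.4 and 18.8 CPM in all fibroblasts, where Lyz2 was at 26.0 and 15.6 CPM, and at 6.48 and 20.4 CPM in modulated smooth muscle cells. Complement genes were higher in smooth muscle cells (0.20, but -0.031 at common cluster shares and -0.072 with a mitochondrial limit of 5%) and below 0 in fibroblasts (-0.10, inside the middle 95% of random lists at percentile 5.16). Stress genes were higher in macrophages (0.10), fibroblasts (0.088) and modulated smooth muscle cells (0.13, but -0.030 when standardised within library) and lower in smooth muscle cells (-0.063). Lysosomal genes were higher in smooth muscle cells (0.074) and lower in fibroblasts (-0.068), and oxidative phosphorylation genes were higher in smooth muscle cells (0.048) and lower in fibroblasts (-0.061). In modulated smooth muscle cells the latter stood at 0.033, inside the middle 95% of random lists (percentile 61.8), and at -0.015 in thinned cells. Matrix remodelling genes stood at 0.073 in macrophages, inside the middle 95% of random lists (percentile 96.6), and were higher in smooth muscle cells (0.13) and lower in modulated smooth muscle cells (-0.10, but 0.045 at common cluster shares). Smooth muscle modulation genes were higher in smooth muscle cells (0.13) and lower in modulated smooth muscle cells (-0.39), and at common cluster shares these were -0.053 and -0.042.

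Of the unnamed clusters, 14 and 18 had larger shares in the M-LipaKI library with intervals apart. The mixed immune cluster 14 held 0.880% of Ctrl and 1.57% of M-LipaKI cells, a ratio of 1.78 (1.22 to 2.63). The shallow stress-gene cluster 18 held 0.307% and 1.10%, a ratio of 3.58 (2.01 to 6.79), and its cells had a median of 1239 UMIs. Cluster 13 went the other way, with 2.64% and 1.95% and a ratio of 0.738 (0.566 to 0.960). The cycling cluster 20 held 0.368% and 0.775%, a ratio of 2.10 (1.19 to 3.88), with share intervals that met, as did those of cluster 13.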

How the results depend on the processing

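Alternatives chosen after seeing the data were doublets by score rank in both libraries, means of per-cluster log2 ratios, state or cluster levels weighted to common shares before 1 ratio was taken, and 10 and 25 neighbours in the macrophage sub-clustering. No paired analysis was possible because each group has 1 library and no result comes from a test. Counting intervals served as the yardstick: of 1858 values under alternatives, 1651 moved within them, 176 moved further and 31 were reversed. Reversed means a change of sign where the main interval lay wholly above or wholly below no difference. Other changes of sign were counted by the size of the move only. The interferon shift in macrophages stayed between 0.41 and 0.61. TMM factors, median-of-ratios factors and totals without genes over 1% of UMIs moved none of 58 values each beyond its interval, and no scaling moved the median of all genes by over 0.1. The cause was not tested for the changes below, except where the setting itself equalises the mix of cells or the depth.

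Many values moved with means of per-cluster log2 ratios (29 moved, 7 reversed), with common cluster shares (17 and 8), with thinned cells (30 and 1) and with a mitochondrial limit of 5% (20 and 3). In macrophages, Cma1, which rests on 1 Ctrl cell, went to a log2 ratio of 1.41 with a mitochondrial limit of 20%, 1.42 with doublets kept, 0.050 at Leiden resolution 0.5 and 1.43 with doublets by score rank. Lyz2 stayed lower, at -0.81, -0.87 and -0.81 with Leiden resolutions of 0.5 and 2.0 and doublets by score rank, at -0.75 in thinned cells and at -0.79 at common state shares, the 1 of 49 macrophage values that left its interval in that setting. Lipa was at 0.032 in thinned cells. Means of per-state log2 ratios gave -0.13 for Gpnmb, -0.20 for Tmem178 and -0.11 for the LXR list. Such means weight states by cells even where a gene has few UMIs, and at common state shares Gpnmb was at 1.75 and Tmem178 at 1.06. Of the 24 named macrophage genes, 3 were kept with a lower UMI minimum, 10 with a higher one and 19 without the filter on other cells.

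In fibroblasts the MHC class II shift was -0.47 with doublets kept and -0.23 with doublets by score rank. The sterol synthesis shift was -0.015 with means of per-cluster log2 ratios, and the interferon shift 0.30 with means of per-cell CPM and 0.34 in thinned cells. In smooth muscle cells a mitochondrial limit of 5% gave -0.030 for interferon and -0.072 for complement genes. Means of per-cluster log2 ratios gave 0.063 for interferon, 0.020 for modulation and -0.029 for complement genes, common cluster shares 0.013, -0.053 and -0.031 for these and -0.0090 for inflammatory cytokine genes, standardising within library 0.40 for interferon and 0.39 for modulation genes, and thinning 0.18 for modulation genes. In modulated smooth muscle cells means of per-cluster log2 ratios gave 0.60 for Ibsp (-1.03 at common shares), -0.15 for interferon, 0.025 for modulation, -0.094 for contractile and 0.090 for matrix remodelling genes. Common cluster shares gave -0.21 for interferon, -0.25 for contractile, 0.045 for matrix remodelling, -0.046 for MHC class II and -0.029 for structural matrix genes. Standardising within library gave 0.029 for matrix remodelling and -0.030 for stress genes, doublets kept -0.032 for contractile genes, and thinning -0.015 for oxidative phosphorylation genes.

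Log2 ratios of class shares moved as well. A mitochondrial limit of 5% gave -0.012 for macrophages and 0.16 for fibroblasts, and standardising within library 0.053 for modulated smooth muscle cells. Shares among immune cells, here macrophages and cluster 14 only, gave -0.055 for macrophages. That value was counted as reversed, although the interval of its ratio (0.849 to 1.09) included 1. Macrophage state shares moved within their intervals at resolutions of 0.3 and 1.0 and with 10 and 25 neighbours. Depth limits the genes near the minimum of 20 UMIs, whose intervals are wide.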

Other observations

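The tests chosen only after the result was seen were those of the paralog, of another cell type, of the state mix, of the share of Gpnmb-led cells and of stress by macrophage state, with the redrawing of cells in the depth test, and the cluster values of the next paragraph were also picked after they were seen.

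Smooth muscle contractile genes showed directions within some clusters that the class as a whole did not. The contractile shift was 0.11 (0.07 to 0.12) in cluster 0, 0.04 in cluster 1, 0.05 in cluster 2 and 0.06 in cluster 4, while the shift of the class was -0.01. Cluster 5, also of this class, was not among the clusters picked. In cluster 12 of the modulated smooth muscle cells the contractile shift was -0.44 (-0.50 to -0.40), with 0 of 16 members above. In the mixed immune cluster 14, Lyz2 was at 10362 CPM in Ctrl and 4325 CPM in M-LipaKI cells and Lyz1 at 679 and 1599 CPM, the directions seen in macrophages. MHC class II genes had a shift of 2.39 in smooth muscle cluster 4 and 5.11 in fibroblast cluster 6.

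The first pattern weighed was higher Lyz1 with lower Lyz2 in M-LipaKI macrophages. A constant share of Lyz2 reads counted as Lyz1 would leave about 58.8 (50 to 68) M-LipaKI macrophages without a Lyz1 UMI, or 87.8 with the share taken without the 5 highest cells, and 406 of 611 had none, which argues against it as the whole cause (an earlier form compared Lyz1 to Lyz2 ratios between states without the proliferating one, whose ratio was 40.8% against 5.62% in Mmp12-led macrophages, and was dropped because few cells hold much of the Lyz1). For a broad strain interval around the Cre insertion, the 62 measured genes within 10 Mb of Lyz2 were read. Their median absolute log2 ratio of 0.11 lay inside the range of random sets (0.0942 to 0.178). This argues only against an interval in which most of these genes differ, since a median hardly moves when a minority does. A strain interval that changes few genes stays open, and a variant at Lyz1 alone was not tested. Cells of another type rich in Lyz1 stay open, since 26.3% (155 of 590) of thinned M-LipaKI macrophages had a Lyz1 UMI, a minority of cells but more than the 4.13% in Ctrl. The Cre insertion in Lyz2 may itself lower Lyz2 and change Lyz1, a hypothesis that 1 library per group leaves untested.

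The second pattern was higher interferon-stimulated genes in M-LipaKI macrophages. Free RNA would add alike to every class, and the summed CPM of the list argues against it for the abundant members. That sum differed by 944 in macrophages (3756 and 4700) and by 33.5 in smooth muscle cells (177 and 210), 28.2 times apart. Ifi27l2a, at 2875 and 3421 CPM in macrophages, made up much of the sum, while the shift is a median over members. Low members were not tested one by one. Stress during dissociation is argued against as the whole cause by proliferating macrophages, where the stress list was at -0.15 (-0.36 to -0.10) and the interferon list at 1.17, and by Mmp12-led macrophages, where they were at 0.52 and -0.08, while a part in other states stays open (an earlier form of this test used smooth muscle cells, where the stress list was at -0.06). A few cells with a strong interferon programme stay open as a part, since the shift was 0.29 (0.22 to 0.41) without the 10% of cells with the highest list share. An effect of Lipa in macrophages, or another difference between the pooled mice, may also underlie it, and none of these was tested. Only M-LipaKI mice carried Cre, so an effect of Cre or of lower Lyz2 cannot be told apart from one of Lipa.

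The third pattern was higher Gpnmb and Ctsk in M-LipaKI macrophages, genes that also mark the Gpnmb-led state. A larger share of Gpnmb-led cells is argued against, since Gpnmb had a log2 ratio of 1.89 (1.69 to 2.08) within that state and the state's share was 10.4% and 10.1%. Another mix of these states is argued against by state shares that hardly differed between the libraries. State levels at common state shares gave a log2 ratio of 1.75 (1.57 to 1.93), but with such shares the weighting could change little. That test replaced a mean of per-state log2 ratios (-0.13) in which states with 0 to 23 Gpnmb UMIs had most of the weight. The intervals of 1.89 and 1.75 cover counting error only and are too narrow, since few cells hold much of the Gpnmb UMIs. Without the 5 highest cells of each library the log2 ratio was 0.99 (0.72 to 1.27), so those cells alone did not make the whole difference. The 5 highest M-LipaKI cells held 71.6% of the UMIs, so its size rests on them. Gpnmb UMIs came from 43 of 433 Ctrl and 64 of 611 M-LipaKI macrophages, and this interval too covers counting error only. A somewhat larger group of high cells therefore stays open. Deeper cells as the whole cause would leave 0 after thinning and are argued against by 1.28 (0.93 to 1.64, or 0.07 to 2.48 with cells redrawn), with Ctsk at 1.73. However, the bound of 1 set beforehand lies inside these intervals, and depth stays open as a part. Lipa overexpression may change lipid handling in these cells, which was not tested. An effect of Cre or of lower Lyz2 cannot be told apart from it in this design.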
